A study of Homo sapiens with 6 samples.

How the data were processed

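RNA was measured in 6 libraries of Jurkat cells, an established human T cell acute lymphoblastic leukaemia line. Of these, 3 carried a control short hairpin RNA (shCtrl) and 3 carried a hairpin directed at SRSF6 (shSRSF6). The group and the replicate number of each library were taken from its title. The treatment text in the labels names the SRSF6 hairpin for all 6 samples, including those titled as controls, so the titles alone separated the groups. The labels' protocols and the series' design text differ on the library kit: the former give poly-A selected, strand-specific libraries read from 1 end, and the latter gives an unstranded kit read from both ends. Neither says whether the replicates came from separate cultures. The p-values below therefore measure the spread between these samples, which may be technical.

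Per the submitters' processing notes, the tools used upstream were bcl2fastq, TopHat, HTSeq and edgeR, with the human genome build hg19. Their versions, their settings and the gene annotation are not given in the sources used here. The deposited table held CPM (gene counts scaled to a common library total) for each gene and library. The authors' own comparison stood beside them: a log2 fold change, an average log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value per gene, per the file headers. Every deposited CPM value was a whole multiple of 1 count to within 2.66e-05 counts, which gave library totals of 45418394, 41718711 and 48286800 counts for shCtrl replicates 1, 2 and 3. The totals for shSRSF6 replicates 1, 2 and 3 were 33952956, 38126390 and 47722568 counts. The fewest counts behind a listed value were 879, in shSRSF6 replicate 1, for which counting error alone is 3.37% of the value. The authors' log2 fold changes differed from the log2 ratio of mean CPM by a near-constant −0.0385 (range −0.0427 to −0.0360, SD 0.000974), so the deposited CPM were scaled by library total alone.

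The table was a selection of the genes the authors tested. It held 1543 protein-coding genes, of which 1000 were listed as lower and 543 as higher, all with an authors' adjusted p-value at or below 0.00995. Lower genes were ordered by their CPM in shCtrl replicate 1, down to 53.2 CPM, and higher genes by their CPM in shSRSF6 replicate 1, down to 48.6 CPM. The rounded p-values in the authors' deposited table imply that about 15515 genes were tested, if the smallest listed p-value was the smallest of all. On that reading about 4227 lay at or below the highest adjusted p-value listed, so the table held roughly 36.5% of those. Its ratio of lower to higher genes is that of a truncated list, and genes outside it are not analysed here. Since the listed genes were chosen by a test on these same libraries, a count of genes that pass a second test on them is not independent evidence of change, and no enrichment against unlisted genes was computed.

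The analysis planned for raw counts was replaced by the one planned for normalized values, since the table held CPM. Values were transformed to log2(CPM + 1), with a filter of at least 1 CPM in at least 3 libraries, which removed 0 genes. Groups were compared with limma 3.58.1 (R 4.3.3), with a mean-variance trend, no covariate, two-sided tests and Benjamini-Hochberg adjustment over the 1543 listed genes, at an adjusted p-value threshold of 0.05. Each gene had 4 residual degrees of freedom before moderation. Fold changes in log2 are on the log2(CPM + 1) scale, which understates changes of low genes, while folds are ratios of mean CPM. Levels are given as mean CPM ± SD over 3 libraries. Coordinates are those of the deposited table, in hg19.

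A total of 35 gene lists were fixed in advance: 26 pathways or complexes, 3 signs of RNA quality and 6 sets of markers of other cell types (B, myeloid, natural killer and cytotoxic, erythroid, epithelial or packaging line, and stromal). The RNA quality lists were mitochondrially encoded RNAs, replication-dependent histones and small nucleolar RNA host genes. The 18 pathway lists with at least 5 listed members were tested with limma's camera against the other listed genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment. Named genes followed a fixed rule: SRSF6, the 10 highest and 10 lowest log2 changes among genes whose groups did not overlap, and up to 4 members of each list with the smallest p-values. The groups, tests, lists, this rule and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 0.5 and 0.1, no filter or a filter at 5 CPM, quantile normalization, a replicate term, limma-voom on the recovered counts, stricter thresholds, leaving out each library, other list tests, removal of GC and transcript length trends, and removal of genes with a sequence word.

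Transcript GC content, length and 3′ UTR sequence came from GENCODE models for GRCh38, matched by gene identifier, with 1 principal protein-coding transcript per gene. They were found for 1526 genes (98.9%), and a 3′ UTR of at least 30 bases for 1519 (98.4%). All 7-base words present in at least 20 of those 3′ UTRs were tested for association with the log2 change after regression on 3′ UTR length and GC content, with 1000 permutations for the family-wise p-value. The scripts were tested on simulated data first. For simulated shSRSF6 against shCtrl libraries of 1543 genes, the gene test recovered 91.0% of 67 genes changed 1.2-fold and 100% of those changed 1.5-fold or 2-fold. It called 12 of 1328 unchanged genes. A list of 15 genes raised 1.2-fold was called and 0 of 17 unchanged lists were. Those lists lay among mostly unchanged genes simulated independently, whereas every listed gene had been selected as changed. The list result therefore does not measure camera's power on the listed genes. The word test found 13 of 20 planted words at a log2 drop of 0.1 and 20 of 20 at 0.3. Further tools were Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.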

Results

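Poly-A RNA was profiled in 3 Jurkat libraries with a control hairpin and 3 with a hairpin against SRSF6, an SR protein that binds exonic enhancers and promotes exon use. Library totals ranged from 33952956 to 48286800 counts. The deposited table listed CPM for 1543 protein-coding genes, which together took 23.5% to 24.1% of the counts in shCtrl libraries and 21.5% to 21.6% in shSRSF6 libraries. Genes outside the table are not analysed here. The comparison asked which transcripts changed in level when SRSF6 was knocked down in these leukaemia cells. It addresses mRNA level only, since the table holds no values per exon.

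The targeted gene fell in every shSRSF6 library. SRSF6 (ENSG00000124193, chromosome 20, 42086568 to 42092245, plus strand, hg19) was at 423, 442 and 427 CPM in the shCtrl replicates and at 256, 249 and 230 CPM in the shSRSF6 replicates. The means were 431 ± 9.97 and 245 ± 13.7 CPM (SD, n = 3 each), a 1.76-fold drop, with a log2 change of −0.81 (SE 0.05, limma adjusted p = 9.13e-08). An exact two-sided permutation test of SRSF6 alone gave p = 0.1, the smallest that 3 against 3 libraries allow. The authors' deposited table gave a log2 fold change of −0.85.

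**Figure D1:**
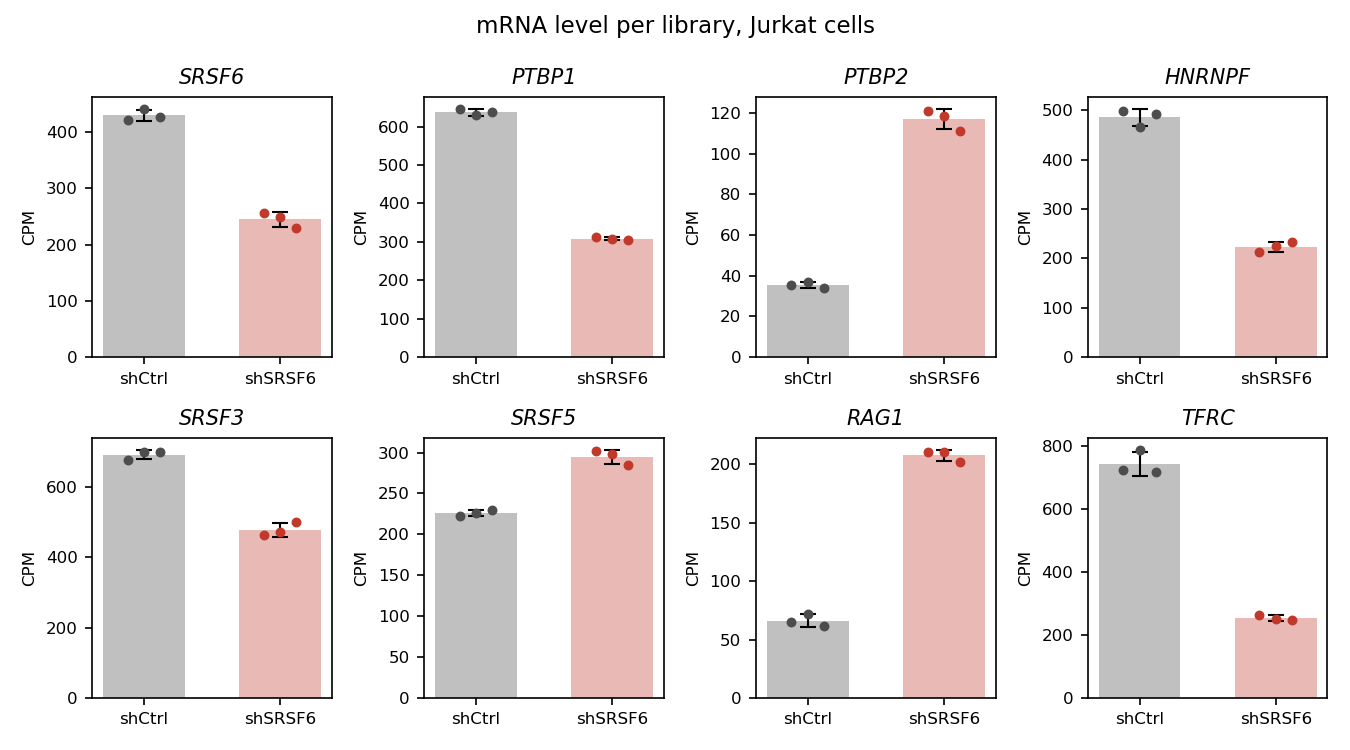
CPM of 8 transcripts in the 6 libraries. Bars show group means, error bars the SD over 3 libraries, and points the single libraries; every vertical axis starts at 0. SRSF6, PTBP1, HNRNPF, SRSF3 and TFRC lay lower in all shSRSF6 libraries, and PTBP2, SRSF5 and RAG1 higher.

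The largest listed rise was that of PTBP2, a neuronal paralogue of the splicing repressor PTBP1. PTBP2 (chromosome 1, 97187221 to 97289294) went from 35.4 ± 1.57 to 117 ± 5.03 CPM (n = 3 each), 3.30-fold higher, with a log2 change of 1.70 (SE 0.05, limma adjusted p = 2.55e-09). PTBP1 itself (chromosome 19, 797075 to 812327) fell from 638 ± 8.59 to 308 ± 3.78 CPM, a log2 change of −1.05 (limma adjusted p = 3.23e-09). RAG1, the catalytic subunit of the V(D)J recombinase, rose from 66.2 ± 5.48 to 208 ± 4.67 CPM, 3.14-fold. The third was SCN3A, a voltage-gated sodium channel subunit, at 33.6 ± 1.51 CPM in shCtrl and 74.1 ± 5.59 CPM in shSRSF6 libraries.

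The other 7 of the 10 largest rises lay between 1.66-fold and 1.80-fold. They were SPON2, a secreted matrix protein, RCBTB2, TNRC6C, a GW182 protein of microRNA silencing, H2AFX, the histone variant phosphorylated at DNA breaks, UCP2, a mitochondrial inner membrane carrier, SIPA1L2 and LENG8. RCBTB2 rose from 32.7 ± 2.72 to 58.9 ± 0.970 CPM and H2AFX from 111 ± 7.01 to 193 ± 12.9 CPM. LENG8 differed most between replicates, at 254, 207 and 144 CPM in shSRSF6 replicates 1, 2 and 3 against 103 to 127 CPM in shCtrl, with a limma adjusted p of 0.00129. None of these 10 genes carried the 6-base sequence GGTGTA in the 3′ UTR. That sequence is part of a word chosen for its tie to lower values over the listed genes. Its absence here thus partly restates that choice.

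The 10 deepest falls all exceeded that of SRSF6. TFRC, the transferrin receptor that brings iron into cells, fell from 742 ± 39.2 to 253 ± 9.32 CPM, 2.93-fold, with a log2 change of −1.55 (SE 0.05, limma adjusted p = 2.55e-09). ARF5, a small GTPase of Golgi transport, fell from 88.5 ± 6.69 to 26.9 ± 0.685 CPM, 3.29-fold. CALM2, which encodes calmodulin, fell 2.76-fold, from 303 ± 8.87 to 110 ± 5.11 CPM. HMGA1, an architectural chromatin protein, fell 2.53-fold to 229 ± 9.02 CPM, and TPD52 fell 2.61-fold to 68.4 ± 3.34 CPM. These 5 transcripts carried the 7-base sequence GGGTGTA in the 3′ UTR, in TFRC within the longer GGGTGTAA. In all, 146 of the 1519 listed genes with an annotated 3′ UTR carried GGGTGTA. This word was chosen among all tested 7-base words for its tie to lower values over these same genes. Finding it, or parts of it, in the deepest falls therefore partly restates that choice. YME1L1, a protease of the mitochondrial inner membrane, TDG, a thymine DNA glycosylase, UBLCP1, a phosphatase acting on the proteasome, and ATP6V1C1, a proton pump subunit, fell 2.56-fold, 2.75-fold, 2.62-fold and 2.45-fold, and carried GGTGTAA there. APLP2, a relative of the amyloid precursor protein, fell 2.46-fold and carried GGTGTA.

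**Figure D2:**
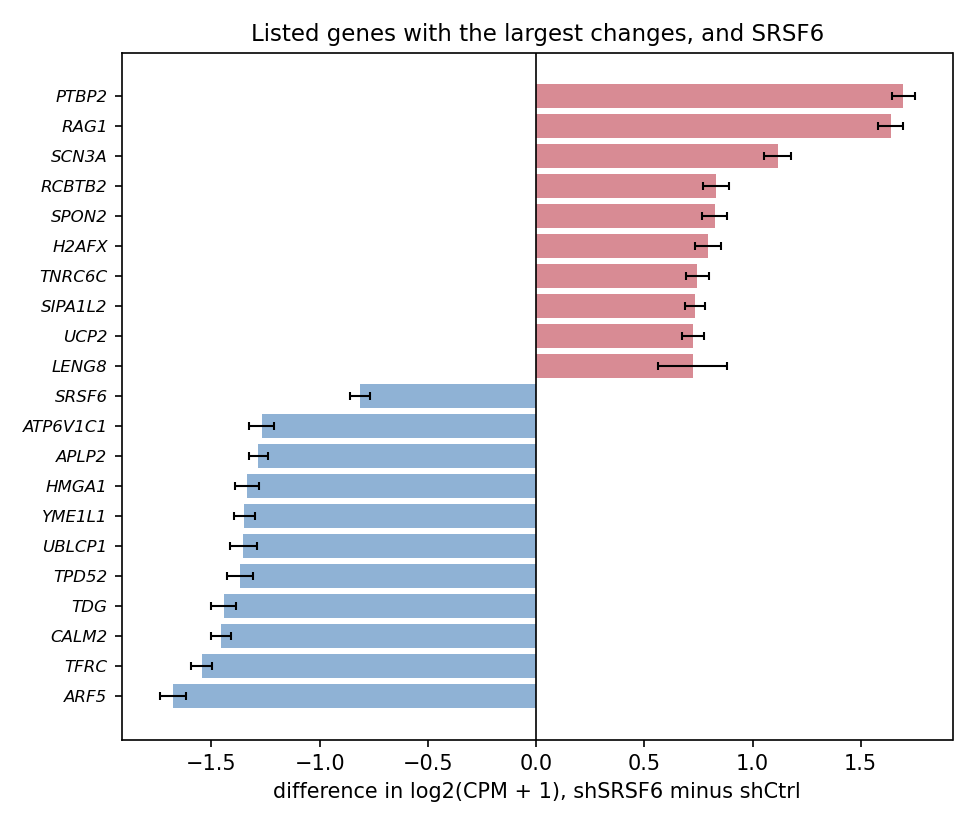
Difference in log2(CPM + 1) between shSRSF6 and shCtrl libraries for the 10 highest and 10 lowest listed genes and SRSF6. Bars are the limma estimates and error bars their standard errors. PTBP2 stands at 1.70 and ARF5 at −1.68, and all 10 falls are deeper than the −0.81 of SRSF6.

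Among splicing factors, most listed members were lower, as were 64.8% of all listed genes. Against the other listed genes, camera's adjusted p was 0.109 for the hnRNP list and 0.188 for the core spliceosome list. Of 8 listed SR proteins, 7 fell and 1 rose. SRSF3 fell from 693 ± 13.3 to 479 ± 19.5 CPM and SRSF2 from 606 ± 9.90 to 489 ± 26.1 CPM, both with GGTGTAA in the 3′ UTR, while SRSF5 rose from 226 ± 3.85 to 295 ± 8.44 CPM. Without SRSF6 itself, 6 of 7 fell (median log2 change −0.23, camera adjusted p = 0.431 against the other listed genes). Of 11 listed hnRNP proteins, 10 fell and PTBP2 rose, with a median of −0.29, although HNRNPA2B1 changed sign under quantile normalization. HNRNPF, which binds G-rich RNA, fell 2.18-fold, from 485 ± 17.2 to 223 ± 9.77 CPM. HNRNPF carried GGGTGTA and PTBP1 GGGTGTAA in the 3′ UTR, and without these genes 8 of 9 members were lower, at a median of −0.26. Of those members, HNRNPH3 still carried GGTGTAA, and HNRNPK, HNRNPDL and HNRNPA1 carried GGTGTA. Alone or within a longer site, GGTGTA lay in the 3′ UTR of 6 of 11 hnRNP genes and 3 of 8 SR genes. Over all listed genes with a 3′ UTR, 1045 of 1519 lacked it, and no test compared these counts. HNRNPK, with GGTGTA, fell from 1079 ± 15.7 to 784 ± 26.2 CPM. Core spliceosome components fell in 12 of 13 cases (median −0.24): SNRPF, an Sm protein, fell 1.28-fold, SNRPA1 1.23-fold, DHX15 1.18-fold and PRPF8 1.17-fold. SF3B1, in that list, changed sign under quantile normalization. Among kinases and phosphatases of splicing factors, 4 of 4 listed members were lower, from PPP1CA at 1.22-fold to PPM1G at 1.10-fold, but under quantile normalization PPP1CC and PPM1G changed sign and 1 of the 4 passed. DYRK2, in that list, had overlapping groups (58.2 ± 4.29 and 51.5 ± 3.13 CPM) and lost its call without shCtrl replicate 2 (limma adjusted p = 0.0751) and without shSRSF6 replicate 3 (0.0896). PPP1CA and DYRK2 carried GGTGTA. Under quantile normalization 5 of 8 SR proteins, 6 of 11 hnRNP proteins and 8 of 13 spliceosome genes passed.

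Protein turnover and ribosome production genes were likewise mostly lower, as were 64.8% of all listed genes. Camera's adjusted p against the other listed genes was 0.109 for each of the USP, proteasome and ribosome biogenesis lists. All 7 listed USP deubiquitinases fell (median −0.34), led by USP22, a subunit of the SAGA complex, which fell 1.66-fold from 430 ± 12.5 to 259 ± 4.86 CPM. USP33 fell 1.48-fold and USP7 1.25-fold, from 535 ± 20.6 to 429 ± 9.66 CPM. All 12 listed proteasome genes fell (median −0.21), among them PSMD12 at 1.49-fold, the proteasome activator subunit PSME2 at 1.29-fold and PSMA5 at 1.19-fold; under quantile normalization 6 of the 12 passed, all lower, as did 6 of the 7 USP genes. Ribosome biogenesis factors fell in 9 of 9 cases (median −0.26), with WDR43 down 1.38-fold and the helicase DDX21 1.43-fold, though under quantile normalization GNL3 changed sign and 5 of the 9 passed. NOP16, which carried GGGTGTAA in the 3′ UTR, fell 1.36-fold. Of 3 listed cytosolic ribosomal proteins, RPL15 fell 1.36-fold, RPS28 rose 1.24-fold and RPS9 rose from 375 ± 24.0 to 451 ± 36.4 CPM; such genes have close copies in the genome. The RPS9 call ended when GC content and transcript length trends were removed (log2 change 0.06, limma adjusted p = 0.0972). It held when a replicate term was added to that correction. Nonsense-mediated decay factors were divided, with 3 higher and 4 lower: UPF3B rose 1.29-fold and SMG5 1.19-fold, while CASC3, of the exon junction complex, fell 1.22-fold. In these groups GGTGTA, alone or within a longer site, lay in the 3′ UTR of 4 of 7 USP genes, 3 of 12 proteasome genes, 3 of 9 biogenesis factors, 2 of 3 ribosomal proteins and 1 of 7 decay factors. These counts were not tested against all listed genes with a 3′ UTR, of which 1045 of 1519 lacked the sequence. USP5 carried GGGTGTA, WDR43, USP12, PSMG1 and MAGOHB carried GGTGTAA, and USP22, USP1, PSMD12, PSMD14, DDX21, RPL15 and RPS28 carried GGTGTA alone.

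Sterol synthesis genes showed the reverse balance, with 10 of 13 listed members higher. SREBF2, the transcription factor that drives the pathway, rose from 246 ± 9.55 to 348 ± 15.5 CPM, and HMGCS1, which makes HMG-CoA, rose from 449 ± 26.3 to 588 ± 7.27 CPM. The falls in this list included SCD, a fatty acid desaturase with GGGTGTA in the 3′ UTR, from 492 ± 12.4 to 277 ± 1.91 CPM. INSIG1, which holds SREBP in the endoplasmic reticulum, fell from 351 ± 14.7 to 193 ± 0.513 CPM and carried GGTGTAA. The median of the list was 0.38, with a camera adjusted p of 0.0716 and an adjusted p of 0.323 with an estimated correlation. Integrated stress and unfolded protein response genes were higher in 5 of 6 cases (median 0.36, camera adjusted p = 0.0716). XBP1 rose 1.38-fold, EDEM1, which targets misfolded glycoproteins for degradation, 1.31-fold, and TRIB3 1.38-fold. HMGCS1 and XBP1 rose although they carried GGTGTAA, and EDEM1 although it carried GGTGTA.

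Genes of T cell biology changed in both directions. All 4 listed members of the T cell identity list rose: RAG1, THEMIS, a regulator of thymocyte selection, from 78.8 ± 5.20 to 110 ± 0.984 CPM, CD1E at 1.24-fold and PTPRC, the phosphatase CD45, at 1.18-fold. Among leukaemia transcription factors, 2 rose and 3 fell. LEF1 rose from 756 ± 2.03 to 935 ± 13.9 CPM, and MYB fell from 538 ± 25.8 to 424 ± 8.01 CPM. In the NOTCH list, 5 fell and 2 rose, with DTX1 down 1.45-fold, NOTCH2 down 1.41-fold and the cell cycle inhibitor CDKN1B up 1.31-fold. TNFAIP3, which restrains NF-kB signalling, rose 1.53-fold and BIRC3, an inhibitor of apoptosis, 1.65-fold; these were the 2 listed NF-kB targets. BCL2 family and caspase genes were higher in 4 of 5 cases (camera adjusted p = 0.109), with CASP8 up 1.47-fold and XIAP, which carried GGGTGTA, down 1.29-fold. JUND was the only listed immediate early gene and rose 1.28-fold, but the call ended when GC content and transcript length trends were removed (log2 change 0.08, limma adjusted p = 0.155). All 4 listed interferon response genes fell, led by OAS3, which carried GGGTGTA, at 1.95-fold. IRF1 fell 1.42-fold and XAF1 1.44-fold. Antigen presentation genes fell in 5 of 5 cases, with the peptide transporter TAP2 down 1.32-fold, but 2 of the 5 passed under quantile normalization, where HLA-B and HLA-C lost their calls. Under that scaling 3 of 4 interferon genes, 3 of 5 leukaemia transcription factors and 6 of 7 NOTCH list genes passed. Of the other genes named here, NOTCH2 and IRF1 carried GGTGTAA, and MYB carried GGTGTA.

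Cell cycle and stress lists were mixed. For G2/M, 11 fell and 4 rose, with CCNA2 down from 238 ± 14.1 to 169 ± 1.82 CPM and the mitotic kinase PLK1 down 1.39-fold; TPX2 changed sign under quantile normalization. For G1/S, 6 fell and 3 rose, the risers being E2F1 at 1.36-fold, E2F2 at 1.27-fold and MCM4 at 1.17-fold, and GINS1 changed sign under quantile normalization. Beside HK2 and GPI below, of the genes named here HSPA4 carried GGTGTAA and CCNA2, MCM4 and XRCC5 carried GGTGTA. DNA damage genes fell in 8 of 10 cases, led by XRCC5, the Ku80 subunit of end joining, from 955 ± 42.9 to 671 ± 19.1 CPM, while the checkpoint kinase CHEK2 rose from 48.6 ± 0.240 to 58.1 ± 0.738 CPM. Of 3 listed p53 targets, TRIAP1 and TNFRSF10B rose 1.28-fold and 1.19-fold and CCNG1 fell 1.19-fold. HSP90AB1, the listed gene with the highest CPM in shCtrl libraries, fell from 2732 ± 42.0 to 1729 ± 30.4 CPM, while HSF1, the heat shock transcription factor, rose 1.38-fold. In the heat shock list 7 fell and 2 rose, but HSPA8, HSPA4 and HSPH1 changed sign under quantile normalization. For glycolysis, 2 rose and 2 fell: HK2, which carried GGGTGTAA, fell 1.60-fold and GPI, also with GGGTGTAA, fell 1.12-fold but changed sign under quantile normalization. Of 8 listed oxidative phosphorylation genes, 6 fell and 2 rose, among them COX7A2 at 1.26-fold, and ATP5A1 changed sign under quantile normalization. The 9 lists of RNA quality and other cell types had 0 listed members, so they could not be assessed. Under quantile normalization 9 of 15 G2/M, 7 of 9 G1/S, 5 of 10 DNA damage, 6 of 9 heat shock, 3 of 4 glycolysis and 3 of 8 oxidative phosphorylation genes passed.

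**Figure D3:**
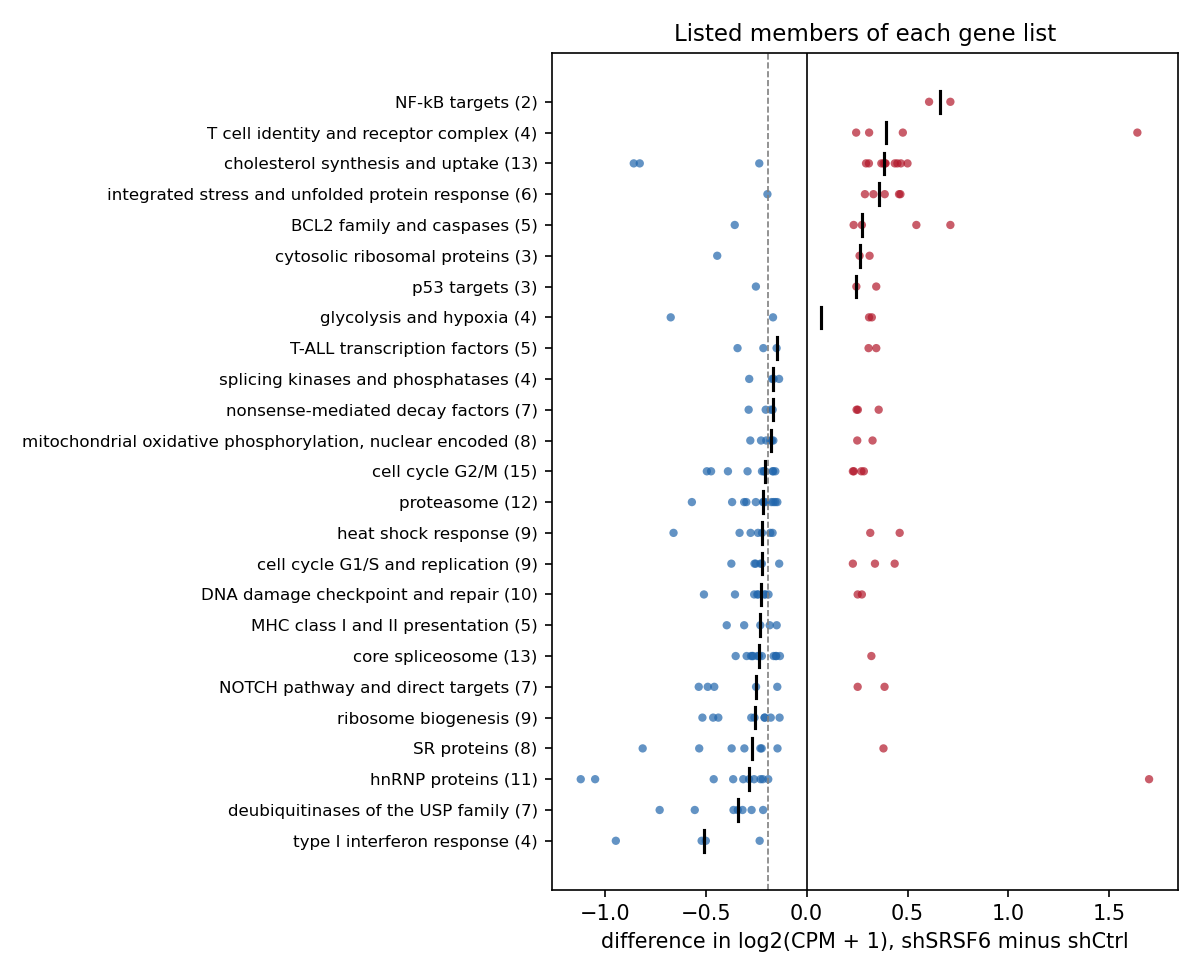
Difference in log2(CPM + 1), shSRSF6 minus shCtrl, for the listed members of 25 gene lists with at least 2 of them (number in parentheses). Points are genes, black bars list medians and the dashed line the median of all listed genes, −0.19. The hnRNP list spans PTBP2 at 1.70 and HNRNPF at −1.12, and the sterol list lies mostly to the right of 0.

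Against the other listed genes, camera called 0 of 18 lists at an adjusted p of 0.05 and 0 with an estimated correlation, with 7 at an unadjusted p under 0.05. Its rank-based form called 4 lists, and Fisher's exact test of direction 1, the sterol list. Fry, which compares a list with no change and not with other genes, called 15 in its one-directional and 18 in its mixed form, in a table whose genes had all been selected as changed. Over the whole table, 1543 of 1543 genes passed (limma, adjusted p under 0.05), 1000 lower and 543 higher, and adjusted over the list alone every listed member of each list passed. In 1509 genes (97.8%) the shSRSF6 and shCtrl libraries did not overlap, which chance gives for 10% of genes. A total of 129 genes, 103 lower and 26 higher, differed by at least 1.5-fold on the log2(CPM + 1) scale. Since the authors selected these genes by a test on the same libraries, the count restates that selection. Quantile normalization, which shifted the median of all listed genes by 0.11 on the log2 scale, gave 629 lower and 546 higher genes. It gives every library the same distribution of values, although the listed genes were selected as changed and were mostly lower. A lost call or a changed sign under it can thus come from that scaling.

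**Figure D4:**
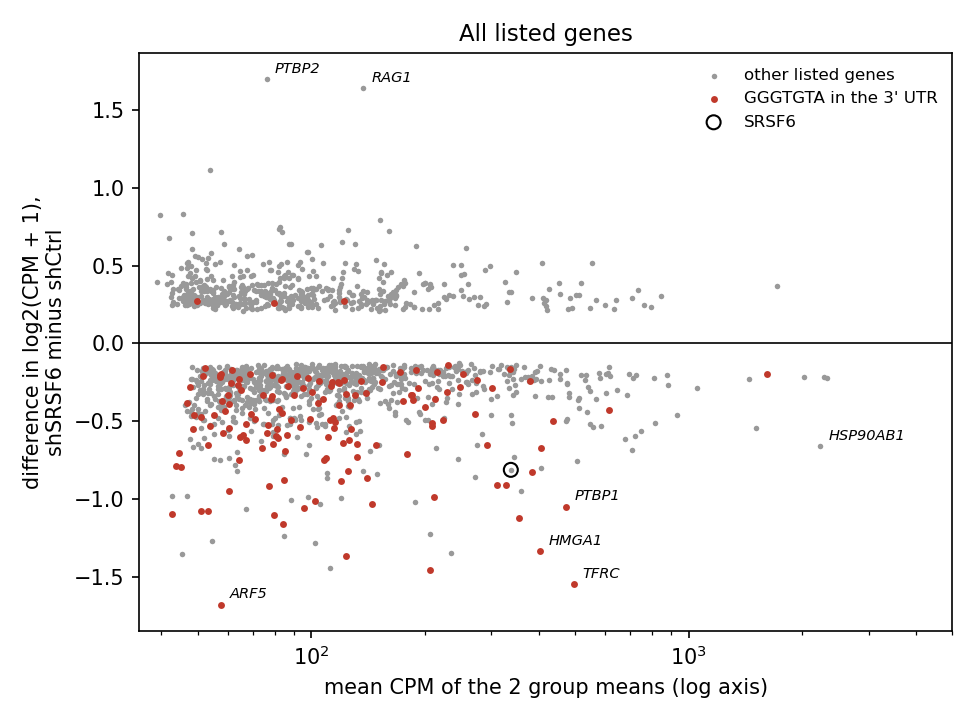
Mean CPM (log axis) against the difference in log2(CPM + 1), shSRSF6 minus shCtrl, for the listed genes. Each point is a gene, red points carry GGGTGTA in the 3′ UTR, and the open circle is SRSF6 at −0.81. Of 146 red points, 143 lie below 0, for a word chosen by its tie to lower values over these genes. The empty band around 0 comes from the authors' selection.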

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

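Tests chosen after the results were seen were the scaling by the authors' constant, Fisher's test of direction, the SR list without SRSF6, the GC and length corrections and the removal of GGGTGTA carriers. The SRSF6 change stayed between −0.85 and −0.63 over 19 alternatives, with a highest limma adjusted p of 1.33e-05. The count of 1543 genes was also given by pseudocounts of 0.5 and 0.1, by limma-voom and by the authors' constant. The filters removed 0 genes, so they tested nothing. An adjusted p under 0.01 kept 1463 genes and GC and length correction, made for the 1526 genes with transcript data, 1506 of 1543. Without the 146 carriers, 1397 of 1397 genes passed. Leaving out a library in turn gave 1512 to 1538 genes (541 to 543 higher, 969 to 995 lower), with 0 sign changes. A fold of at least 1.5, taken on the log2(CPM + 1) scale, gave 129 genes, 26 higher and 103 lower, by its construction. Quantile normalization gave 629 lower genes and 40 sign changes. Of named genes, PPP1CC went to 0.0256, PPM1G to 0.0168, GPI to 0.0599 and ATP5A1 to 0.00929. By giving every library the same distribution of values, it moved the median log2 change of the mostly lower listed genes from −0.19 to −0.08. Which of the sign changes came from that scaling alone was not tested.

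Camera's 0 lists became 4 with ranks, 1 with Fisher's test, 1 with GC and length correction and 1 without carriers, and 0 to 2 when a library was left out. Adding a replicate block to the GC and length correction returned the count to 0. One-directional fry called 15, but it tests for no change rather than against other genes, and every listed gene had been selected as changed. The 2 lists came without shCtrl replicate 3, namely the sterol and stress response lists (both adjusted p = 0.0467), and the single ones were the sterol list. With an estimated correlation and all 6 libraries, camera gave both of these lists an adjusted p of 0.323. Of 113 named genes other than SRSF6, 101 kept their sign and their side of the threshold in all alternatives except the 1.5-fold one, which 83 missed.

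Whether the replicate numbers pair the samples could not be settled. The study design's words on matched pairs do not say that replicate numbers mark a shared day. Same-numbered libraries had deviations correlated at −0.00375, 0.148 and 0.436, and not every library correlated best with its own number. Deviations were taken from each group's own mean, so these correlations constrain each other and cannot exclude pairing. A replicate block gave 1543 genes (543 higher, 1000 lower), 1520 with GC and length correction. Not run were the quality and other-cell-type list tests, which had 0 members. The other size-factor normalizations and the negative binomial tests, with their fold threshold, were left out with the plan for counts, although the recovered counts of the listed genes would allow them. Counting error reached 3.37% at the fewest counts, 879 in shSRSF6 replicate 1, and the median replicate SD was 0.07 log2 for shCtrl and 0.04 for shSRSF6.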

Other observations

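The gene families in this part and the comparison of site types were chosen after the results were seen, as were DNTT and the variable genes; the tests of sequence words, GC content, length and sample splits were fixed before their results. Symbols formed 21 families with at least 6 listed members outside chromosome Y. Only translation initiation factors and their regulators (EIF) passed Fisher's exact test of direction at an adjusted p under 0.05. Their median log2 change, −0.23, was near the −0.19 of all listed genes, and the test takes genes as independent. All 16 listed members fell, against 64.8% of listed genes (Fisher's exact test, adjusted p = 0.0237, two-sided). EIF4H, which aids the helicase EIF4A, fell 1.93-fold, EIF4G2 1.46-fold, EIF2A 1.40-fold and EIF5B, which joins ribosomal subunits, 1.38-fold. None carried GGGTGTA in the 3′ UTR, but EIF4H, EIF5B and EIF5 carried GGTGTAA and EIF2B5 and EIF3M carried GGTGTA. Under quantile normalization EIF3M and EIF4A2 changed sign and 9 of the 16 passed as lower. All 9 nuclear pore genes (NUP) were lower too, with NUP153 at 1.28-fold and NUP133 at 1.28-fold (adjusted p = 0.328), as were all 8 kinesins (adjusted p = 0.396). NUP153 and the kinesins KIF1B and KIF14, which fell most in that family, carried GGGTGTA, and NUP133 and KIF21B carried GGTGTA. Under quantile normalization NUP50, which carried GGTGTAA, and NUP188 changed sign, and 5 NUP and 4 KIF genes passed as lower. Beside RAG1, DNTT, the polymerase that adds untemplated bases during V(D)J recombination, rose from 62.8 ± 3.43 to 104 ± 5.29 CPM (n = 3 each), with a log2 change of 0.72 (limma adjusted p = 9.71e-07).

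For the 47 listed genes that fell by more than SRSF6, with a median log2 change of −1.02, a candidate explanation is off-target repression through the hairpin's seed: of 14852 words of 7 bases, GGGTGTA in the 3′ UTR was most tied to lower values (family-wise p = 0.000999, the smallest that 1000 permutations can give), and 25 of 46 such genes with a 3′ UTR (54.3%) carried it against 8.21% of the others. The word was chosen for its tie to lower values over these same genes, so the 54.3% largely restates that choice. The medians were ordered as for small RNA sites: −0.55 for 51 genes with GGGTGTAA, −0.45 for 95 with GGGTGTA alone, −0.31 for 128 with GGTGTAA, −0.22 for 200 with GGTGTA and −0.16 for 1045 with none of these, a group that still held 7 of the 46. These medians rest on the same word and were not adjusted for 3′ UTR length or GC content. The SRSF6 transcript carries GGGTGTA 1 time, at position 550 before the 3′ UTR, as a hairpin target ending in that word would, while 15.4% of listed transcripts carry it anywhere. Regression on GC content and transcript length kept 96.2% of the pattern's distance from the mean. This argues against a trend with GC content or length over the listed genes as the whole cause. The 47 genes were picked by their change, so that share largely follows from the weak tie of the change to GC content (Spearman's rho 0.21) and length (−0.07). Genes with the word only before the 3′ UTR showed 30.9% of the drop (95% bootstrap interval 17.4% to 47.7%), which leaves open how far the word acts outside the 3′ UTR. The hairpin sequence is not given in the sources used here, so loss of SRSF6 itself, or a change in a factor that binds this word, stays open as untested, and PTBP1, HNRNPF, TFRC and HMGA1 are among the genes this concerns. The same question reaches beyond the 47 genes: 143 of 984 lower genes with a 3′ UTR carried GGGTGTA, against 3 of 535 higher genes. Of genes with GGTGTAA 90.6% were lower, and of those with GGTGTA alone 73.0%, against 55.4% with none of these sites. The word was chosen on the changes of all these genes, so these counts and shares also partly restate that choice.

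The SD over listed genes of the log2 ratio between libraries of the same group ranged from 0.06 to 0.14. By this measure shCtrl replicate 2 and shSRSF6 replicate 3 stood farthest from their partners. Among genes SEC31B, at 85.5, 73.7 and 47.1 CPM in the shSRSF6 replicates, varied most. GC content and transcript length may both contribute: across listed genes, which are not independent replicates, Spearman's rho with GC content was −0.86 for shCtrl replicate 2 against the other two and −0.333 for shSRSF6 replicate 1 against 3, and with length 0.42 and 0.407. The change between groups followed GC content less, at 0.21, and length at −0.07. No biological explanation of this spread was tested.

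For the count of 1543 genes past the threshold, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave that many, and the highest other split gave 0. The 10 splits are too few for a share under 0.05, and the genes had been selected on the real split.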
